A study of Homo sapiens with 6 samples.

How the data were processed

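Genomic DNA methylation was measured by whole-genome bisulfite sequencing in 6 libraries of MCF-7, an oestrogen-receptor-positive human breast cancer cell line. Bisulfite converts unmethylated cytosine to uracil, so that a cytosine read after conversion is counted as methylated. Per the labels, 3 libraries came from cells infected with a lentivirus carrying sh-UHRF1 and 3 from cells infected with an sh-Scramble lentivirus, the control. Per the labels' protocols, the DNA carried a lambda DNA spike, was sonicated to 200 to 300 bp and was treated with bisulfite before library construction. The conversion rate and the read depth are not given in the sources used here. Nothing in the labels says whether the libraries of a group came from separate cultures.

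Per the submitters' processing notes, CASAVA, FastQC 0.11.5 and Bismark 0.16.3 were used. The tool that called the regions is not given in the sources used here. The table analysed lists 13472 differentially methylated regions for sh-UHRF1 against sh-Scramble, each in 1 cytosine context (CG, CHG or CHH, where H is A, C or T). The methylation levels are fractions, given as 1 mean per region and group, per the file headers. How the authors took the mean over cytosines, reads and libraries is not stated. Other deposited columns give the region length, the number of cytosines and the difference of the group levels, which the authors computed as sh-UHRF1 minus sh-Scramble. The signed area statistic is a score that the authors deposited for each region, with the sign of the difference in 13472 of 13472 regions. It was used only to rank and filter regions within this list, and it favours regions with many cytosines, as CHH regions mostly are.

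No values per library were available to the analysis, so each level is the authors' group mean without a spread between replicates, and no region was tested anew. The depth behind each level is unknown, and no interval that needs it is given. The list holds called regions only, so it does not show the methylation of the rest of the genome. It holds exactly 10000 CHH regions. In the authors' deposited table, the smallest absolute area statistic was 385.849 for CHH regions, 12.1 for CG regions and 15.5 for CHG regions. CHH regions also held at least 52 cytosines, against at least 4 in CG and in CHG regions. The counts of CHH regions therefore describe a list that may have been limited by rank.

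The processing notes name GRCh37, but the coordinates are on GRCh38. The table names scaffolds and patches of GRCh38, and its last regions end at 83205823 on chromosome 17 and 155999237 on chromosome X, beyond the GRCh37 ends of both. At the deposited coordinates, 43.4% of lower CG regions overlapped a gene edge, against 11.6% after a shift of 10000 bp and 10.8% after a shift of -10000 bp. Gene names, biotypes and positions came from a RefSeq gene table for GRCh38.p14, with 59084 genes on chromosomes 1 to 22 and X. The gene analyses used the 13245 regions on those chromosomes. The other 227 regions (1.68%) lay on 100 scaffolds and patches.

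A region was assigned to each gene that it overlapped by at least 1 bp, or whose ends lay within 2000 bp. The gene table had no strand and no exons, so the promoters planned for the analysis were replaced by gene edges, and neither exon, intron nor UTR is given. A gene edge was the window from 2000 bp outside to 500 bp inside either end of a gene. Each region was classed as at a gene edge, elsewhere in a gene, or outside genes, using protein-coding and lncRNA genes. Shares of regions carry Wilson 95% intervals, which cover counting error over regions only. Lower and higher regions were compared by two-sided Fisher's exact tests over regions, with Benjamini-Hochberg adjustment over 4 tests (all contexts, CG, CHG and CHH). Regions are not replicates of the cultures, so these tests describe the list.

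The 15 fixed gene lists were DNA methylation machinery, tumour suppressors methylated in breast cancer, oncogenes, cancer-testis antigens, imprinted genes, HOX genes, developmental regulators that polycomb binds, clustered protocadherins, luminal and oestrogen-response genes, basal and mesenchymal markers, blood and endothelial markers, interferon and viral sensing, WNT signalling, cell cycle and apoptosis, and long axon and synapse genes. A further 7 families were taken by symbol: zinc finger (ZNF), olfactory receptor, cancer-testis, HOX, keratin, microRNA (MIR, host genes included) and LINC genes. For each, the number of members with a region was compared with 100000 random lists of the same size (one-sided permutation test, smallest possible p 1e-05). These were matched on gene class (protein-coding, lncRNA or any other) and on 20 bins of gene length within the class. Genes of the last class, microRNAs included, were thus matched together across biotypes. The number of CG sites in a gene was not matched. Length was matched only to the bin, so the longest genes shared a bin with shorter ones. Genes with only lower regions against genes with any higher region were compared between the list and all other genes with a region by a two-sided Fisher's exact test. Both sets of p were adjusted by Benjamini-Hochberg over the 22 lists and families, with a threshold of 0.05. Whether the regions of a gene shared a direction was tested by 2000 permutations of directions within the chromosome (smallest possible p 0.0005).

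The genes to be named were set by rule. They were, per direction, the 10 gene-edge regions and the 5 regions elsewhere in genes with the largest absolute area statistic, the 5 genes with the most regions, up to 4 members of each list with gene-edge regions first, and 7 methylation genes (UHRF1, DNMT1, DNMT3A, DNMT3B, TET1, TET2 and TET3). The rule was applied to all contexts and again to CG regions. The lists, the naming rule, the tests and most alternatives were chosen before the data were examined. Alternatives comprised stricter differences and area statistics, a cytosine minimum, autosomes only, CG regions only, merging of close regions, each chromosome left out, other edge windows, other gene assignments and other matching. The CG versions of these settings and several others were added after the data had been seen.

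The list tests and the permutation of directions were tested on simulated data, in 5 sets of 1725 CG regions and the annotation of 59084 genes. Every simulated region started inside a protein-coding or lncRNA gene, and the lists were drawn at random from such genes. The rates below thus do not cover regions outside genes, microRNA genes of other biotypes or lists of clustered genes. With region placement raised 4-fold in 20 lists of 60 genes, 13 lists were recovered at an adjusted p under 0.05, and 2 of 80 unplanted lists were called. Fisher's exact test recovered 7 of 10 lists with a planted direction and called 0 of 90 others. These 10 lists also had raised placement, and nearly all regions placed in them were set lower. The rate thus does not cover weaker shifts of direction or lists with few regions. The permutation of directions called 5 of 5 sets with shared directions and 1 of 5 sets with random directions. Where directions were shared, all regions placed in a gene went the same way, so partial sharing was not tried. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and matplotlib 3.10.9 for the plots.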

Results

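The data were whole-genome bisulfite sequencing of MCF-7 cells, an oestrogen-receptor-positive breast cancer line, infected with an sh-UHRF1 or an sh-Scramble lentivirus (3 libraries each). UHRF1 binds hemimethylated CG sites and recruits DNMT1, the enzyme that copies CG methylation after replication. The comparison asks where DNA methylation differed between cells with the UHRF1 hairpin and control cells. The deposited list holds 13472 regions, of which 1807 (13.4%) are CG, 1665 (12.4%) are CHG and 10000 (74.2%) are CHH regions. Each methylation level below is the authors' mean over a group. Without values per library, no difference could be set against the spread between replicates, and the depth is unknown.

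CG methylation in sh-UHRF1 cells was lower in some regions and higher in slightly more. Of the CG regions, 824 (45.6%, Wilson 95% interval 43.3 to 47.9%) were lower in sh-UHRF1 and 983 (54.4%) were higher. The median difference was -17.3 percentage points in lower and 18.0 percentage points in higher CG regions. Median levels were 47.6% in sh-Scramble and 26.0% in sh-UHRF1 in lower regions, and 40.0% and 63.2% in higher regions. Most started from intermediate methylation: sh-Scramble levels lay between 20 and 80% in 75.2% of lower and 73.9% of higher CG regions. Only 63 lower CG regions (7.65%) had an sh-Scramble level of at least 80%. The differences reached 20 percentage points in 284 lower (34.5%) and 362 higher (36.8%) CG regions. CG regions were short, with a median of 97 bp and 18 cytosines in lower and 99 bp and 18 cytosines in higher regions.

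Outside CG, nearly all regions were lower in sh-UHRF1. This held for 1539 of 1665 CHG regions (92.4%, 91.1 to 93.6%) and 9414 of 10000 CHH regions (94.1%, 93.7 to 94.6%). Their levels were low: lower CHH regions had a median of 4.01% in sh-Scramble and 0.250% in sh-UHRF1, and lower CHG regions 5.14% and 0.139%. The 586 higher CHH regions had a median of 0.238% in sh-Scramble and 4.01% in sh-UHRF1. All contexts together gave 11777 lower regions (87.4%, 86.8 to 88.0%) and 1695 higher ones. This share was set by the CHG and CHH regions, and the balance turned to more higher than lower regions in CG alone. The conversion rates, which set the background of non-CG levels, are not given in the sources used here. Of CHH regions, 66.4% were 200 to 300 bp long, the size of the sonicated DNA. Every listed CHH region had an absolute area statistic of at least 385.849 and at least 52 cytosines. This favours long regions, so the length does not point to single fragments. Unconverted single fragments stay open as a source of these levels, and region length does not decide.

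**Figure D1:**
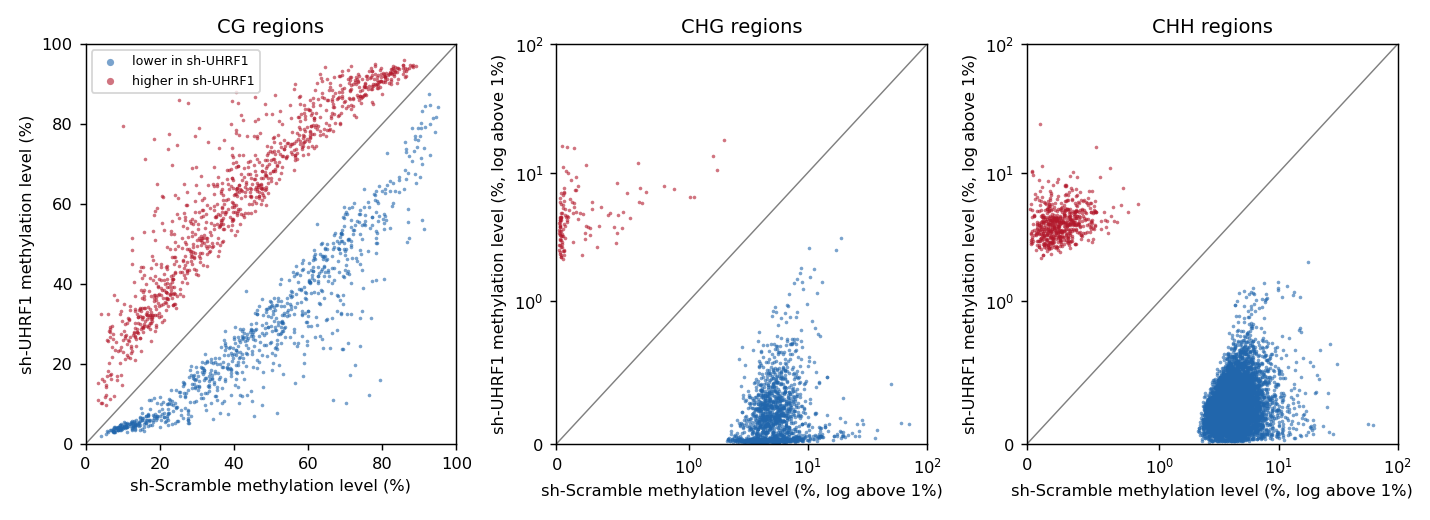
Methylation level of each region in sh-Scramble (horizontal axis, percent) and sh-UHRF1 (vertical axis, percent), with 1 point per region and 1 panel per context; CHG and CHH axes are logarithmic above 1%. Points below the grey line of equal levels (blue) are lower in sh-UHRF1, as were 824 CG, 1539 CHG and 9414 CHH regions, and points above it (red) are higher.

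Genes of the methylation machinery had regions about as often as matched genes. No region was assigned to UHRF1, DNMT1, DNMT3B, TET1 or TET2. The list holds no RNA or protein levels, so the knockdown itself was not measured. DNMT3A, a de novo methyltransferase, had 4 regions: a CG region inside the gene (chr2:25340564-25340720) with 72.6% in sh-Scramble and 91.0% in sh-UHRF1, and 3 lower CHH regions. TET3, which oxidises 5-methylcytosine, had 2 lower regions, 1 CHG (6.79% to 0.216%) and 1 CHH (2.91% to 0.165%). Of the 18 genes of this list, 5 had a region of any context, against 4.80 in matched random lists (adjusted permutation p = 0.807).

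At gene edges, the lower CG regions with the largest area statistics lay at genes of several kinds. At CHST11, a chondroitin sulfotransferase, the level was 32.3% in sh-Scramble and 12.7% in sh-UHRF1 (chr12:104457027-104457423). VGLL3, a cofactor of TEAD transcription factors, had 66.5% and 40.2% (chr3:86990493-86990907), and PAQR5, a membrane progesterone receptor, had 27.8% and 8.52% (chr15:69298961-69299348). The calcium-dependent kinase gene CAMK2D was at 48.8% and 27.7% (chr4:113761499-113761844). A region shared by OBSL1 and the inhibin gene INHA was at 53.4% and 32.4% (chr2:219570850-219571224). ASCL2, a basic helix-loop-helix factor, was at 56.2% and 32.6% (chr11:2268909-2269229), and FZD10, a WNT receptor, at 69.8% and 50.2% (chr12:130162573-130162898). VOPP1 (12.6% and 3.55%, chr7:55572285-55572553), OLFML2A (49.3% and 32.1%, chr9:124777103-124777542) and A3GALT2 (71.6% and 54.3%, chr1:33307192-33307473) completed the set.

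Higher CG regions at gene edges were led by SVIL, which encodes the actin-binding protein supervillin, with 42.0% in sh-Scramble and 67.6% in sh-UHRF1 (chr10:29736648-29737125). CDK14, a cyclin-dependent kinase, was at 38.0% and 68.4% (chr7:90596163-90596501). A4GALT, the Gb3 glycolipid synthase, was at 13.2% and 33.7% (chr22:42720717-42721029). The transcription factor genes HOXD8 (27.2% and 43.2%, chr2:176129937-176130375) and FOXF2 (9.99% and 23.1%, chr6:1389887-1390116) were also higher. So were the matrix genes LAMC3, a laminin chain (13.8% and 28.8%, chr9:131009085-131009384), and P4HA3, a collagen prolyl hydroxylase (12.7% and 27.1%, chr11:74311384-74311837). The remaining edge regions were at SORT1 and PSMA5, which share a region (31.7% and 44.8%, chr1:109397551-109397997), MID2 (21.1% and 38.6%, chrX:107826163-107826530) and PGBD5 (23.9% and 39.2%, chr1:230425950-230426260).

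Lower CG regions were at gene edges more often than higher ones. Of 784 lower CG regions, 43.4% were at edges, 34.1% elsewhere in genes and 22.6% outside. Of 941 higher CG regions, the shares were 35.5%, 41.1% and 23.4%. The odds ratio for an edge was 1.39 (95% interval 1.15 to 1.69; Fisher's exact test, p = 9.00e-04, adjusted p = 0.00180). Among differences of at least 20 percentage points, the odds ratio was 0.927 (exact p = 0.702), and the call was lost. Within quartiles of the sh-Scramble level it was 1.51 (1.24 to 1.84), and within quartiles of the mean level of both groups 1.14 (0.928 to 1.40). Both levels enter the difference that sets the direction. CHH regions were at edges in 9.96% of lower and 8.12% of higher cases (odds ratio 1.25, adjusted exact p = 0.229), and CHG regions in 12.7% and 13.3% (odds ratio 0.942, adjusted exact p = 0.777). Pooling all contexts gave the opposite sign, with 12.6% of lower and 24.2% of higher regions at edges (odds ratio 0.450, adjusted exact p = 7.34e-32), because lower regions were mostly CHH.

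**Figure D2:**
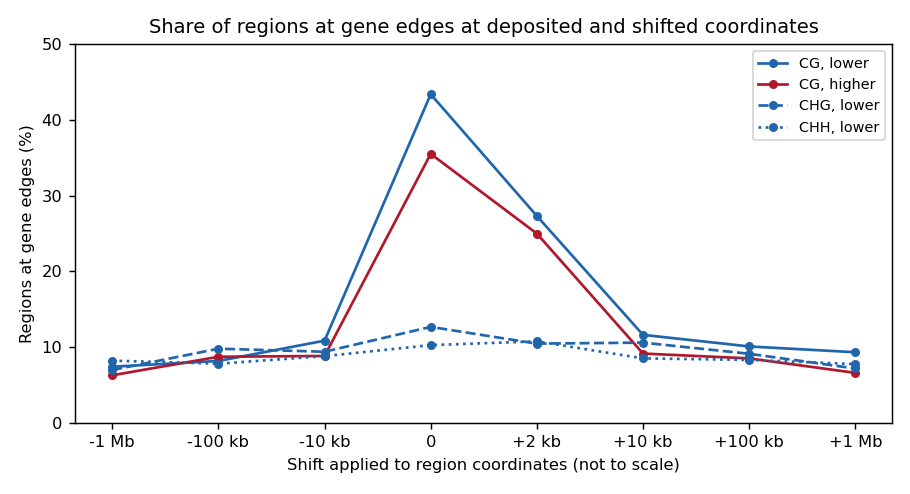
Share of regions at gene edges (vertical axis, percent) at the deposited coordinates (0) and after shifting every region along the chromosome (horizontal axis, not to scale), for CG lower, CG higher, CHG lower and a random sample of 2000 CHH lower regions. CG regions peak at 43.4% (lower) and 35.5% (higher) at a shift of 0, while the CHH line stays between 7.75 and 10.8%.

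Inside genes, the lower CG regions with the largest area statistics were at L3MBTL3, a methyl-lysine reader (42.7% in sh-Scramble and 16.2% in sh-UHRF1, chr6:130019750-130019989), and ABLIM1, an actin-binding protein (32.7% and 12.9%, chr10:114768021-114768349). SAXO5 (34.8% and 21.4%, chr19:7500993-7501334), the haem transporter gene SLC48A1 (24.7% and 9.26%, chr12:47773361-47773600) and the semaphorin gene SEMA6D (38.3% and 19.9%, chr15:47718205-47718568) followed. Higher ones were at FOXQ1, a forkhead factor (46.6% and 64.4%, chr6:1313549-1313834), GAREM2 (35.7% and 57.6%, chr2:26184860-26185114) and TMTC1 (50.05% and 74.2%, chr12:29783624-29783853). The calcium channel gene CACNA1A (53.4% and 71.9%, chr19:13207233-13207541) and CREB3L1 (30.8% and 50.9%, chr11:46295401-46295911) were higher as well. In all, 1663 genes had a CG region, of which 761 had only lower, 796 only higher and 106 both kinds.

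Several genes held many CG regions. SORBS2, an adaptor of the actin cytoskeleton, had 8, of which 4 were lower and 4 higher. TBX1, a T-box factor of pharyngeal development, had 7 CG regions, 1 lower and 6 higher. At the edge of TBX1 the level was 10.5% in sh-Scramble and 28.2% in sh-UHRF1 (chr22:19756943-19757202). AUTS2, a neurodevelopmental gene, and SIPA1L1 had 6 each, 1 lower and 5 higher, and TENM3, a teneurin, had 6, 2 lower and 4 higher. Among 167 genes with at least 2 CG regions, 51.5% had all in a single direction, against 45.6% after permutation (permutation p = 0.0810). With all contexts, 76.0% of 1939 genes did so, against 71.7% after permutation (permutation p = 0.0005, the smallest possible). With overlapping regions, most of them CHG and CHH pairs, counted once, 72.1% of 1665 genes did so, against 71.0% after permutation, and the call was lost (permutation p = 0.146). It remained when the permutation was also kept within context (permutation p = 0.00800). With every region of all contexts counted, CSMD1, FHIT and SORCS2 had the most (20 each), followed by CAMTA1 and KAZN (18 each), nearly all of them CHG or CHH.

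**Figure D3:**
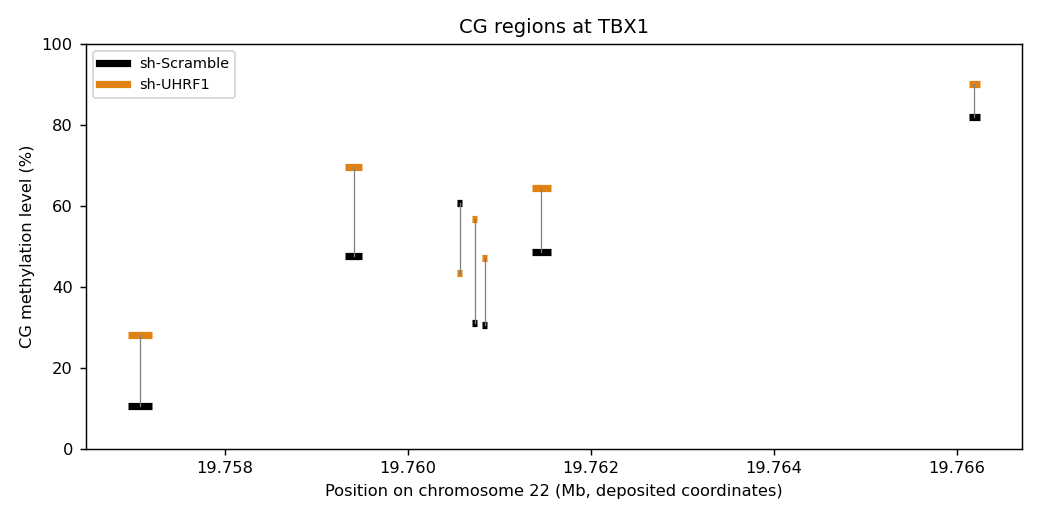
CG regions at TBX1 by position on chromosome 22 (horizontal axis, Mb) with the methylation level (vertical axis, percent) in sh-Scramble (black bars) and sh-UHRF1 (orange bars); bar width is the region and grey lines join both levels. Of the 7 regions, 6 are higher and 1 is lower in sh-UHRF1.

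Developmental regulators that polycomb binds carried CG regions more often than genes matched on class and length. The random lists were not matched on the number of CG sites, and polycomb binding was not measured here. Regions were found at 17 of 127 members, against 5.36 in random lists (adjusted permutation p = 8.80e-04). The 27 regions comprised 8 lower and 19 higher ones, and 5 genes had only lower regions while 12 had a higher one. TBX1 alone held 7 of the 27, 1 lower and 6 higher. That balance did not pass against other genes (adjusted p = 0.701, Fisher's exact test). ASCL2 (56.2% in sh-Scramble and 32.6% in sh-UHRF1) and the homeobox gene BARX1 (61.5% and 47.1%, chr9:93955029-93955221) had lower edge regions. TBX1 (10.5% and 28.2%) and the forkhead gene FOXC2 (15.5% and 28.1%, chr16:86567101-86567280) had higher ones. Of 42 HOX genes, 3 had a CG region, each of them higher, against 1.57 in random lists (adjusted permutation p = 0.449). These were HOXD8, HOXD9 (23.3% and 46.7%, chr2:176122935-176123167) and HOXC4 (83.0% and 94.6%, chr12:54054289-54054360). The HOX family by symbol gave the same 3 members of 39 (adjusted permutation p = 0.449).

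Long axon and synapse genes also carried an excess of CG regions, at 21 of 66 members against 10.7 in random lists (adjusted permutation p = 0.00456). This list was made of long genes, and length within a bin was not matched. The test therefore does not separate an excess of the list from gene length. The excess did not pass in the upper part by area statistic (8 against 6.004, adjusted permutation p = 0.833) or at 20 percentage points or more (10 against 4.50, adjusted permutation p = 0.0608). There were 11 lower and 24 higher regions. Only lower regions were found in 6 genes and a higher one in 15, which did not pass against other genes (odds ratio 0.470, adjusted exact p = 0.701). AUTS2 was at 13.1% in sh-Scramble and 28.0% in sh-UHRF1 at its edge (chr7:69598403-69598699), and the NMDA receptor gene GRIN2B at 40.2% and 59.7% (chr12:13982084-13982193). Lower edge regions were at CSMD1 (51.2% and 22.2%, chr8:4994634-4994691) and the calcium channel gene CACNA1B (81.4% and 72.7%, chr9:137877899-137877951). MicroRNA genes and their hosts passed with 30 of 1984 members against 18.5 (adjusted permutation p = 0.00293), in 16 lower and 13 higher regions. MIR9-2HG had 36.0% and 74.0% (chr5:88674068-88674170), MIR3659HG 17.9% and 30.9% (chr1:38046809-38046883), and MIR193BHG 7.37% and 3.46% (chr16:14302870-14302973). The microRNA excess was lost at 20 percentage points or more (7 against 4.39, adjusted permutation p = 0.270) and when each region was given to 1 gene only, and with gene-edge regions alone no list had an excess of CG regions.

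The clustered protocadherins, neuronal adhesion genes that share overlapping gene models, had 13 of 53 members with a CG region, against 4.03 in random lists (adjusted permutation p = 0.00110). All 13 rest on a single region of 59 bp at PCDHGB5 (chr5:141398241-141398299) with 45.0% in sh-Scramble and 23.2% in sh-UHRF1, which also lies inside PCDHGA1, PCDHGA2 and PCDHGA3. Its direction test passed (adjusted exact p = 8.03e-04) for the same reason. Neither call remained when each region was given to 1 gene. Imprinted genes, which are methylated by parental origin, had 7 of 55 members with a CG region, against 2.97 (adjusted permutation p = 0.0921), and passed with random lists matched on length alone (adjusted permutation p = 0.0492). The region shared by PEG10 and SGCE was at 39.2% and 17.1% (chr7:94655822-94656051), NAA60 at 43.8% and 26.6% (chr16:3442503-3442624), and GNAS, the Gs alpha locus, at 15.2% and 36.5% (chr20:58888946-58889264). GNAS, PEG10 and SGCE each had a further CG region in the opposite direction.

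Cancer gene lists showed no excess of CG regions. Among 58 tumour suppressors methylated in breast cancer, 3 had one, against 3.87 in random lists (adjusted permutation p = 1). These were TIMP3, an inhibitor of metalloproteinases (34.4% in sh-Scramble and 20.3% in sh-UHRF1, chr22:32801725-32801913, with 2 higher regions beside it), COL6A2 (63.4% and 43.3%, chr21:46097738-46097829) and KEAP1 (12.2% and 24.5%, chr19:10502388-10502526). Of 38 oncogenes, 4 had a CG region, against 2.49 (adjusted permutation p = 0.469). FGFR1 (21.0% and 35.0%, chr8:38467960-38468207) and JUN (21.9% and 36.2%, chr1:58782423-58782656) had higher levels at these regions, and CDK6 (32.0% and 18.5%, chr7:92835911-92835972) and the cyclin gene CCND1 (8.86% and 3.49%, chr11:69639253-69639314) lower ones. The 4 cell cycle and apoptosis genes with a CG region of 58 were lower at each region, against 3.03 in random lists (adjusted permutation p = 0.607). They included the apoptosis gene BID (42.5% and 21.4%, chr22:17774305-17774545) and CCND3 (73.0% and 46.4%, chr6:42048788-42049028).

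Lineage markers went both ways. Luminal and oestrogen-response genes had a CG region in 5 of 40 members, against 2.37 in random lists (adjusted permutation p = 0.265), in 5 lower regions and 1 higher. The mucin gene MUC1 was at 20.4% in sh-Scramble and 9.98% in sh-UHRF1 (chr1:155194700-155194886), ADCY9 at 8.80% and 3.60% (chr16:4116009-4116074) and IGF1R at 65.2% and 49.97% (chr15:98852431-98852484). The higher region was inside ADCY9 (64.2% and 86.6%, chr16:4087883-4087955), and it was the only one of these with a difference of at least 20 percentage points. Basal and mesenchymal markers had one in 6 of 38 members, against 2.29 (adjusted permutation p = 0.0921), and passed with random lists matched on length alone (adjusted permutation p = 0.0379). TWIST2 (57.7% and 38.8%, chr2:238847787-238847941), ITGB4 (44.6% and 30.1%, chr17:75721387-75721438) and MMP2 (80.8% and 62.8%, chr16:55479025-55479079) were lower, and TGFBI was higher (47.4% and 66.5%, chr5:136029004-136029180). Of 24 blood and endothelial markers, CD79A (30.6% and 62.7%, chr19:41882869-41883089) and ITGAM (26.8% and 56.0%, chr16:31316050-31316163) had higher CG regions, against 1.15 members in random lists (adjusted permutation p = 0.588).

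WNT signalling had a CG region in 5 of 65 members, against 4.12 (adjusted permutation p = 0.622). FZD10 and LRP5 (13.0% in sh-Scramble and 5.46% in sh-UHRF1, chr11:68312519-68312571) were lower, and WNT5A (30.4% and 53.9%, chr3:55482083-55482402) and DKK1 (21.6% and 33.4%, chr10:52315015-52315066) higher. Zinc finger genes had 32 of 560 members with a CG region, against 27.0 (adjusted permutation p = 0.449), among them ZNF274 (23.6% and 34.7%, chr19:58183259-58183500) and ZNF611 (50.8% and 30.7%, chr19:52734618-52734764). LINC genes had 45 of 2305, against 54.9 (adjusted permutation p = 1), and passed when each region was given to 1 gene (32 against 18.7, adjusted permutation p = 0.00887). The methylation machinery had 1 of 18, DNMT3A, against 1.07 (adjusted permutation p = 0.981). No CG region was found at the 73 cancer-testis antigens, the 43 interferon and viral sensing genes, the 417 olfactory receptors, the 112 genes of cancer-testis families or the 68 keratins, against 3.13, 1.67, 9.61, 3.58 and 2.08 members in random lists. The test counts an excess only, so these zeros carry no test of depletion.

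Over all contexts, CHH regions led the ranking of lower regions and of regions elsewhere in genes, while the CG regions at SVIL and CDK14 led the higher regions at gene edges. Lower CHH regions held a median of 89 cytosines, against 18 in lower CG regions. Their median area statistics per cytosine were -5.44 and -4.73, and their median differences -3.74 and -17.3 percentage points. The ranking across contexts thus does not follow the size of the change. At gene edges, lower CHH regions with the largest area statistics were at TH, tyrosine hydroxylase (5.83% in sh-Scramble and 0.378% in sh-UHRF1, chr11:2172391-2172977), GADD45B, a stress-response gene (5.54% and 0.892%, chr19:2479347-2479731), and CARTPT, a neuropeptide gene (5.60% and 0.201%, chr5:71718953-71719326). POU5F2, GALNT16-AS1, DMKN, MUC5B-AS1, CACTIN-AS1, TSPAN32 and PRICKLE2-DT had lower CHH regions with sh-Scramble levels from 4.46% at DMKN to 9.71% at CACTIN-AS1. Elsewhere in genes, ELN, the elastin gene (13.2% and 0.1105%, chr7:74048968-74049291), ABHD6 (11.1% and 0.347%, chr3:58292205-58292587), NOL4L, KLHL29 and GPC1 were lower. Higher CHH regions were at the homeobox gene SHOX2 (0.112% and 7.67%, chr3:158106068-158106336), TCP11, TNS1 and LINC02810, and inside PGR, the progesterone receptor gene (0.171% and 5.48%, chr11:101053580-101053829). KCNA6, KCNQ1 (0.139% and 4.55%, chr11:2561418-2561731), MICALL1 and CAMTA1 also had higher CHH regions.

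Over all contexts, 6 lists had more members with a region than random lists. Long axon and synapse genes had 59 of 66 against 43.8 (adjusted permutation p = 2.20e-04), imprinted genes 24 of 55 against 13.1 (adjusted permutation p = 0.00257), and tumour suppressors 26 of 58 against 16.1 (adjusted permutation p = 0.00779). For the long axon and synapse genes, length within a bin was again not matched. WNT genes had 28 of 65 against 17.6 (adjusted permutation p = 0.00829), microRNA genes 95 of 1984 against 73.3 (adjusted permutation p = 0.00269), and protocadherins 30 of 53 in only 3 regions against 17.2 (adjusted permutation p = 7.70e-04). In CHG and CHH regions alone, microRNA genes (68 against 55.8, adjusted permutation p = 0.0841) and protocadherins (17 against 14.9, adjusted permutation p = 0.810) lost the excess, and the other 4 lists kept it. With each region given to 1 gene, imprinted genes (18 against 11.7, adjusted permutation p = 0.0743), microRNA genes (25 against 28.8) and protocadherins (3 against 16.1) lost the call, while polycomb-bound regulators and LINC genes passed. At the imprinted locus of DLK1 and MEG3, edge CHH regions were at 6.98% in sh-Scramble and 0.489% in sh-UHRF1 (DLK1) and 3.67% and 0.300% (MEG3). SFRP2, a WNT antagonist on both the tumour suppressor and WNT lists, had 5.86% and 0.104%. Polycomb-bound regulators (adjusted exact p = 0.00702), axon and synapse genes (adjusted exact p = 1.05e-04) and zinc finger genes (adjusted exact p = 0.0386) had fewer genes with only lower regions than other genes, and protocadherins had more (adjusted exact p = 0.0264). Zinc finger genes lost this call with at least 10 cytosines per region, and protocadherins lost it with each region given to 1 gene. Within CG, polycomb-bound regulators, axon and synapse genes and zinc finger genes had no such call (adjusted exact p = 0.701 each). In CHG and CHH regions together, a split made after the data had been seen, axon and synapse genes had it (odds ratio 0.186, adjusted exact p = 1.22e-05). Polycomb-bound regulators (odds ratio 1.03, adjusted exact p = 1), zinc finger genes (adjusted exact p = 0.863) and protocadherins (adjusted exact p = 0.863) did not. The pooled calls of polycomb-bound regulators, with 27 CG regions of 45, and zinc finger genes thus mix contexts. Of 5 keratins with a CHG or CHH region, 3 had a higher one (adjusted exact p = 0.0477). With the largest region per gene, only polycomb-bound regulators kept the pooled call. Axon and synapse genes (odds ratio 0.851, adjusted exact p = 0.904), zinc finger genes (adjusted exact p = 0.445) and protocadherins (adjusted exact p = 0.197) lost it, and a gene with many regions has more chances of a higher one. Gene edges alone left 1 list with an excess, microRNA genes, and none with a difference in direction.

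The other lists did not pass over all contexts. Members with a region numbered 11 of 38 oncogenes, 6 of 73 cancer-testis antigens, 7 of 42 HOX genes and 28 of 127 polycomb-bound regulators (adjusted permutation p = 0.0630). They numbered 12 of 40 luminal genes, with TFF1 at 4.72% in sh-Scramble and 0.417% in sh-UHRF1 in a CHH region, 12 of 38 basal markers and 3 of 24 blood markers. They numbered 2 of 43 interferon genes, APOBEC3G and RSAD2, both lower, and 14 of 58 cell cycle genes. By family, they numbered 103 of 560 zinc finger genes, 4 of 417 olfactory receptors, 4 of 112 cancer-testis family genes, 7 of 39 HOX genes, 5 of 68 keratins and 323 of 2305 LINC genes.

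CHG and CHH regions were mostly lower on every chromosome, while the CG share lay on either side of 50%. More than 50% of regions were lower on 23 of 23 chromosomes for both CHG and CHH, with CHH shares from 91.8% on chromosome 6 to 97.0% on chromosome 15. For CG, the share was under 50% on 18 chromosomes and over 50% on 5, from 26.7% on chromosome 13 to 58.2% on chromosome X. These 2 shares rest on 45 and 67 CG regions. Whether the CG share differed between chromosomes beyond counting error was not tested. Chromosome 19 was densest in each context, with 1.89 CG, 1.16 CHG and 6.13 CHH regions per Mb, against medians over chromosomes of 0.551, 0.520 and 3.27. Copy number, which is altered in MCF-7, was not analysed here.

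**Figure D4:**
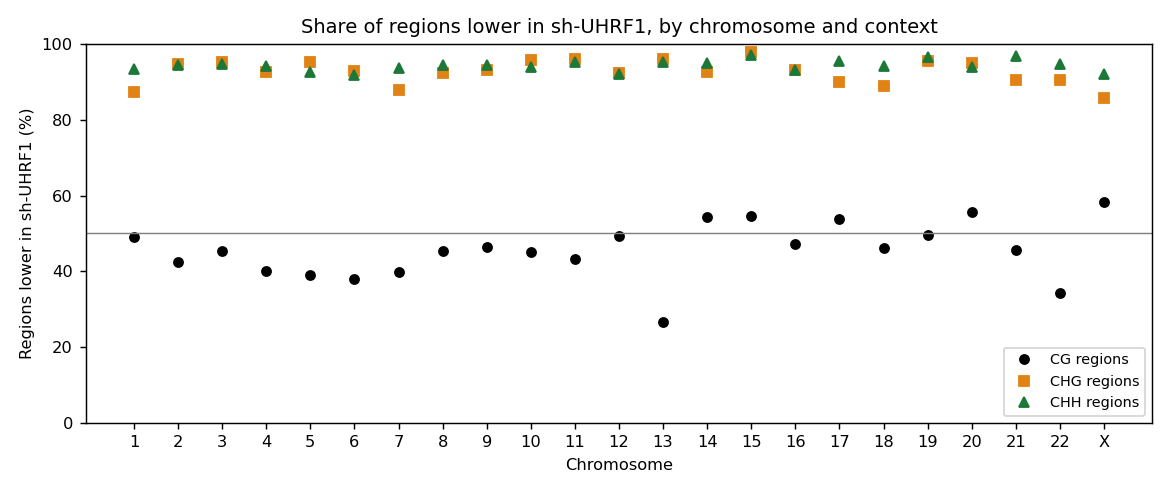
Share of regions lower in sh-UHRF1 (vertical axis, percent) on each chromosome (horizontal axis) for CG (circles), CHG (squares) and CHH (triangles) regions, with a grey line at 50%. CHG and CHH lie above the line on 23 of 23 chromosomes, and CG lies below it on 18.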

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

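The regions on scaffolds and patches took no part in the gene comparisons, and they were looked at only after the main results were known. They hold 42 CG regions that were higher in sh-UHRF1 and 40 that were lower. Scaffold KI270733.1 alone holds 10 CG regions, 5 in each direction. One of them, at 129734 to 130330, was at 6.52% in sh-Scramble and 29.4% in sh-UHRF1. All 3 CG regions of scaffold GL000220.1 were lower, at 51.5% and 7.70% (150977 to 151316), 37.3% and 10.7% (107015 to 107395), and 38.9% and 24.3% (118572 to 118877). All 3 CG regions of GL000218.1 were higher. Both KI270733.1 and GL000220.1 are known to carry ribosomal DNA repeats, whose copies share reads, and no explanation was tested for these values.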

How the results depend on the processing

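The CG versions of the settings, CHG or CHH alone, the split of nested genes, matching on length alone, protein-coding genes only, removal of scaffolds, permutation within context, overlapping regions counted once, list tests in CHG and CHH alone and the CG test of regions per gene were chosen after the data had been seen. No paired analysis was possible because only group means were given, with no column for a single library. For the same reason, leaving out each replicate was not run. Depth per region is unknown, so no result was limited to well covered regions, and where a value moved the cause was not tested.

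The share of lower regions over all contexts (87.4%) turned to 46.3% at differences of at least 20 percentage points and 45.6% in CG alone. It was 94.0% in the upper part by area statistic, 88.8% with at least 10 cytosines, 90.8% by covered bases, 92.4% in CHG and 94.1% in CHH. Without 1 chromosome it ran from 87.2 to 87.6%. For CG regions the share kept its side in all 30 alternatives, from 44.0 to 46.3%.

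Median differences over all contexts (-3.97 and 12.2 percentage points) became -25.1 and 24.3 at 20 points or more, -3.92 and 4.10 in the upper part by area statistic, and -3.93 and 10.1 with at least 10 cytosines. They became -17.3 and 18.0 in CG alone, and -3.79 and 4.45 when weighted by cytosines. In CG regions, -17.3 and 18.0 became -25.1 and 24.4, -15.8 and 16.6, -16.3 and 16.996, and -16.1 and 16.9 under these same settings, CG alone aside.

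The odds ratio for gene edges over all contexts (0.450) was 0.867 at 20 points or more (exact p = 0.508) and 1.39 in CG alone. For CG regions (1.39) it was 0.927 at 20 points or more (exact p = 0.702) and between 1.34 and 1.43 in the other 7 alternatives, with exact p from 3.99e-04 to 0.0117.

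Lists with an excess over all contexts numbered 6. At 20 points or more there were 3, polycomb-bound regulators, zinc finger genes and protocadherins, of which only protocadherins were among the 6. There were 3 in the upper part by area statistic (tumour suppressors, WNT, axon and synapse genes), 1 with gene edges only (microRNA genes) and 12 with unmatched random lists. In CHG and CHH together 4 of the 6 remained, without microRNA genes and protocadherins, and each region to 1 gene gave 5. CG lists with an excess (4) numbered 3 at 20 points or more (polycomb-bound regulators, protocadherins and zinc finger genes), 2 in the upper part by area statistic (polycomb-bound regulators and microRNA genes), 0 with gene edges only and 7 unmatched, without microRNA genes. They numbered 3 with each region to 1 gene (polycomb-bound regulators, axon and synapse genes and LINC genes) and 6 matched on length alone, which added imprinted genes and basal markers. Lists with a difference in direction (4) numbered 1 at 20 points or more and in CG alone (protocadherins), 1 in the upper part by area statistic (axon and synapse genes), 1 with the largest region per gene (polycomb-bound regulators), 2 in CHG and CHH together (axon and synapse genes and keratins) and 0 with gene edges only. With at least 10 cytosines the 4 became 3, without zinc finger genes, and with each region to 1 gene they became 3, without protocadherins. The CG list with a difference in direction was lost (0) in the upper part by area statistic, with gene edges only and with each region to 1 gene. The share of genes with regions in a single direction (76.0%) lost its call with overlapping regions counted once (72.1%, permutation p = 0.146) and in CG alone (51.5%, permutation p = 0.0810), where gene bodies only gave 55.6% (permutation p = 0.0100). With overlapping regions counted once and directions permuted within chromosome and context, the call remained (permutation p = 0.00800). Autosomes only added polycomb-bound regulators to the lists with an excess over all contexts (7). Each chromosome left out, merging and the other edge windows turned no direction.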

Other observations

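Among the tests below, those of unconverted fragments, of a single library or batch, of UHRF1-dependent non-CG methylation, of small differences, of a single chromosome, of conversion throughout the sh-UHRF1 libraries and of starting methylation level were chosen after the results had been seen.

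Neighbouring CG regions of a gene sometimes went in opposite directions, in examples chosen after their values were seen. At TIMP3, a lower region (34.4% in sh-Scramble and 20.3% in sh-UHRF1) lay between higher ones at 32.6% and 48.9% (chr22:32801396-32801543) and 11.5% and 26.0% (chr22:32802081-32802195). At GNAS, a region at 28.4% and 17.2% (chr20:58888560-58888720) lay beside the one at 15.2% and 36.5%. FOXC2 had a lower region (36.0% and 21.5%, chr16:86567649-86568083) between higher ones at 15.5% and 28.1% and at 17.4% and 33.7% (chr16:86568587-86568928). At PEG10 and SGCE, the lower region at 39.2% and 17.1% was followed by a higher one at 18.3% and 41.1% (chr7:94658110-94658207).

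Other polycomb-bound regulators with higher CG regions were ASCL1 (16.0% in sh-Scramble and 34.1% in sh-UHRF1), SIM2 (49.3% and 72.8%), IRX5 (21.5% and 40.0%) and TBX3 (14.1% and 30.2%). SOX1 had 2 higher regions, at 38.1% and 66.1% and at 47.3% and 65.1%. LHX2 (34.7% and 15.1%), FOXG1 (69.4% and 42.1%) and PAX6 (46.8% and 34.6%) had lower ones. The 20 non-CG regions with the highest level included 19 lower and 1 higher, and 15 lay outside genes. Several are overlapping CHG and CHH regions of the same place, on chromosomes 7, 9, 14, 18 and 21, so they are not independent. How uniquely reads map there was not checked. The highest were a CHG region at 70.7% and 0.143% (chr18:18714761-18715045) and a CHH region at 61.8% and 0.134% (chr7:60362297-60362566).

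Nearly all non-CG regions were lower in sh-UHRF1, which could be technical. Chromosome domains of non-CG methylation stay open: 11.6% of lower CHH regions had another within 10 kb, above the mean of 6.66% and the highest of 7.55% in 100 random placements. The ratio of 1.75 lay under the bound of 2 set beforehand, but that bound rested on no measured domain size. Unconverted single DNA fragments in the sh-Scramble libraries stay open too. The CHG level was 1.11 times the CHH level in the median of 797 overlapping pairs. Both rest on the same reads, and true methylation of the place could give the same. Of CHH regions, 66.4% were 200 to 300 bp long, the sonication size, and 99.92% were at most 600 bp. Only 4.62% of CHG regions were 200 to 300 bp long. Region length does not decide either, since every listed CHH region had an absolute area statistic of at least 385.849, which favours long regions. A single sh-Scramble library or a library batch and UHRF1-dependent non-CG methylation cannot be told apart, since 0 columns hold values of a single library.

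More CG regions were higher than lower in sh-UHRF1. Small differences near the authors' threshold are argued against, since 44.0% (40.2 to 47.8%) of CG regions were lower at 20 percentage points or more. The share stayed at 46.1% or less without any 1 chromosome. Incomplete conversion throughout the sh-UHRF1 libraries, large enough for the median gain of 18.0 percentage points in higher CG regions, is argued against as well. CHG and CHH regions had a median of 0.253% in sh-UHRF1 (upper quartile 0.366%), but most are listed for being lower there. Those listed for being higher had sh-UHRF1 medians of 4.01% (CHH) and 4.45% (CHG), also under 18.0%. A smaller failure is not addressed, since the list shows no unselected background. An effect of the UHRF1 hairpin, separate drift of the infected cultures or unconverted fragments at these places alone may lie behind the balance, and none was tested.

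Lower CG regions were at gene edges more often than higher ones. This excess was lost among differences of at least 20 percentage points (odds ratio 0.927, Fisher's exact test, p = 0.702). The number of cytosines per region is argued against as the cause, since the odds ratio within quartiles of cytosine number was 1.46 (1.18 to 1.81). An effect of methylation level stays open: the odds ratio was 1.51 (1.24 to 1.84) within quartiles of the starting level in sh-Scramble and 1.14 (0.928 to 1.40) within quartiles of the mean level of both groups. Both levels enter the difference that sets the direction, so neither test decides.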
